A study of Mus musculus with 40 samples.

How the data were processed

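Bone marrow was taken from the femurs and tibiae of 10 mice on a mixed C57BL6/129Ola background, aged 46 to 51 days, per the labels. In 5 mice both Mbd3 alleles were deleted (Mbd3del), and the 5 control mice carried intact alleles flanked by recombination sites. Mbd3 encodes a subunit of the NuRD complex, a chromatin remodelling and histone deacetylase complex. From every mouse 4 populations were sorted by flow cytometry, which gave 8 groups of 5 libraries and 40 libraries in all. Haematopoietic stem cells (HSCs) were sorted as CD45-positive, CD150-positive, CD48-negative and EPCR-positive cells. The other 3 populations were lineage-negative with surface Sca-1 and c-Kit and high Flt3. Of these, lymphoid-primed multipotent progenitors (LMPPs) lacked the interleukin 7 receptor, all-lymphoid progenitors (ALPs) carried it without Ly6D, and B cell-biased lymphoid progenitors (BLPs) carried it with Ly6D. Each library was made from a pool of sorted cells by Smart-seq2, a full-length cDNA method without molecular identifiers that does not mark the strand, followed by a Nextera XT preparation. The sample labels give 150 cells per HSC pool and 100 per pool of the other populations, whereas the series design text gives the numbers the other way round, so cell number differs between populations but not between genotypes. The titles of the Mbd3del LMPP libraries call the allele floxed, while their genotype and description fields call it deleted; the latter were followed and checked against Mbd3 itself.

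The authors deposited 1 table of raw read counts per gene for all 40 libraries. Reads were aligned to GRCm38 with STAR 2.5.2b and counted with HTSeq 0.6.1p1, per the submitters' processing notes. The annotation release, the strand setting and the meaning of rows named repRegion are not given in the sources used here. The table holds 128910 rows, of which 49585 are genes and 79325 are repRegion rows. The repRegion rows took 0.205% to 2.28% of a library's counts and stayed out of library sizes and of all gene tests. Of the gene rows, 49326 identifiers matched GENCODE M21, from which symbols and coordinates were taken, 259 had no symbol and 19632 had no count in any library. Coordinates are 1-based on GRCm38. Counts do not record which part of a gene was read, and the deleted part of Mbd3 is not given in the sources used here, so reads from exons that remain may still be counted. Counts of genes in multigene families, such as Ly6c2, the surrogate light chain gene Vpreb2 and the immunoglobulin variable segments, are uncertain because similar copies can share or lose reads. Counts of genes that overlap another gene are uncertain too, since strand was not marked.

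Gene counts per library ranged from 2974305 to 9082610. A count of 3 over a library corresponds to 0.330 to 1.01 CPM (counts scaled to equal library totals). Intervals on ratios of counts are 95% and, like the floors, cover counting error only, because amplified reads are not independent molecules. Where a whole group had 0 counts, a fold is a lower bound against 3 counts over the group.

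The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, TMM scaling, the default expression filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a single gene comes from this test unless another tool is named. Each of 13 comparisons was fitted on its own libraries: genotype in each population (Mbd3del over control, 5 against 5), the steps HSC to LMPP, LMPP to ALP and ALP to BLP within each genotype, and the difference of each step between genotypes (interaction). The 20 gene lists, with 329 genes that all matched, were NuRD complex, sort markers, B lineage, lymphoid priming, T lineage, thymus homing, stem cell, neutrophil and monocyte, erythroid, megakaryocyte and platelet, mature B and plasma cell, NK and innate lymphoid, dendritic cell, macrophage, stromal and endothelial, cell cycle, p53 targets, interferon response, immediate early and heat shock, and imprinted. Lists with at least 3 tested members were tested with camera of limma 3.58.1, which compares a list with the other genes, at a preset correlation between genes of 0.01, then with an estimated correlation, and adjusted over the lists of a comparison. A B lineage score was the mean log2(CPM + 1) over the list per library, tested by a two-sided exact permutation test over 252 arrangements, whose smallest possible p is 0.00794. The designs, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Mbd3, up to 10 genes per direction of each genotype comparison, 6 of each control step and 5 of each interaction, taken by fold among genes past the threshold with a mean of at least 5 CPM in the higher group. Except for interactions, all libraries of one group had to lie above all of the other, and unnamed gene models were left out. Called list members may be named, with up to 4 as examples, and where a list had none, 1 or 2 of lowest p. Sort markers and NuRD members may always be named, and any other gene is said to be chosen after its values were seen.

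The libraries of a step come from the same mice, so mouse pairs them. In the data, deviations from group means of libraries from the same mouse correlated across genes at 0.0229 on average (range -0.178 to 0.137), against -0.00546 for libraries of other mice. Of 40 libraries 16 correlated best with another of their own mouse, where chance gives 8. The fit with mouse as a block is an alternative. No pair of libraries within a group was a duplicate: the smallest chi-square per degree of freedom over 80 pairs was 22.6.

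Alternatives were DESeq2 1.42.0 size factors, no scaling, no filter, a filter at 50 counts, the DESeq2 Wald test, limma voom with quality weights, a fit without robust estimates, labelled sex or sex and age as covariates, a joint fit of all 40 libraries, the mouse block, other pseudocounts and list sizes, and leaving out each library or mouse. Chosen after seeing the data were edgeR's newer quasi-likelihood estimator, fits without control mouse10372 and mouse10381, whose sex-linked transcripts go against their labels, an average genotype effect over the 4 populations (limma on each mouse's mean log2 CPM), tests of the repRegion rows, and tests with Mbd3, whose change the genotype fixes, left out of the genes or of the NuRD list. The list tests with libraries left out were also chosen after seeing the data. The programs were tested on simulated counts with 200 changed genes. In the simulated genotype comparisons 4% to 16% of genes changed 2-fold were recovered, 32% to 60% of those changed 4-fold, 78% to 88% at 16-fold and 86% to 96% at 64-fold, all with the right sign, and 3 to 8 unchanged genes were called. In the simulated interactions 0% to 4% were recovered at 2-fold and 14% to 30% at 4-fold. The simulated genotype fits called 106 to 133 genes, whereas the real ones called 2 to 8. With fewer calls the adjustment asks for a smaller p, so these shares can overstate recovery in the real fits. With camera a simulated raised list of 28 genes was called and an unchanged list was not. The simulated genes varied independently, so this does not test camera on lists whose members vary together. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.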

Results

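RNA was profiled in pools of sorted bone marrow cells from 5 control mice and 5 mice in which Mbd3 was deleted, with HSCs, LMPPs, ALPs and BLPs taken from every mouse. The populations follow the path from the stem cell through lymphoid-primed and all-lymphoid stages to progenitors biased towards B cells. The comparisons ask what loss of Mbd3 changes at each stage, how expression changes from each stage to the next, and whether those steps differ between genotypes. Each library held between 2974305 and 9082610 gene counts and 12845 to 15745 detected genes. Mitochondrial transcripts took 2.35% to 7.75% of the counts and the 10 most counted genes 4.66% to 12.03%. Of 24 exact permutation tests of library measures between genotypes, the smallest unadjusted p was 0.0476, for more detected genes in Mbd3del LMPPs (14280 ± 373 against 13528 ± 518, SD, n = 5 each), with an adjusted p = 0.852. Across all libraries the first principal component held 49.7% of the variance of the 1000 most variable genes and the second 9.02%.

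**Figure D1:**
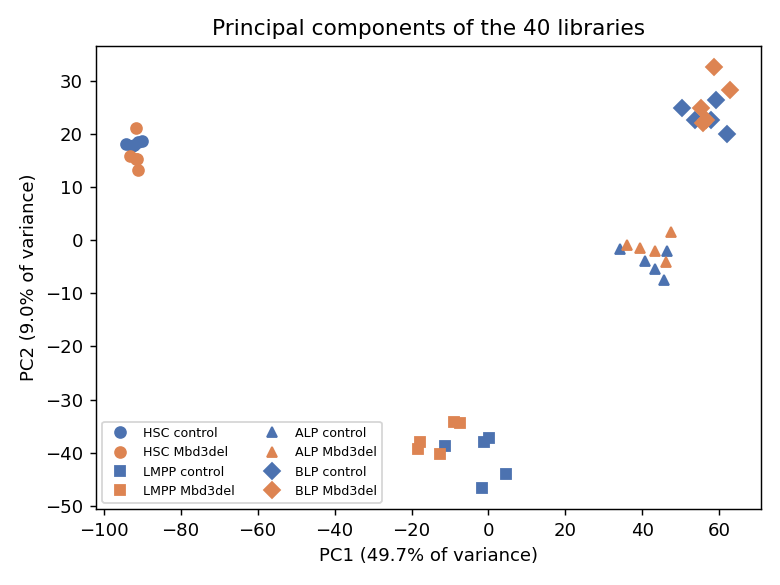
Libraries on the first 2 principal components of log2 CPM over the 1000 most variable genes, which hold 49.7% and 9.02% of the variance. Each point is 1 of 40 libraries, coloured by genotype and shaped by population, and libraries lie by population along the first component.

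Transcripts of sex-linked genes matched the labelled sex in 8 of the 10 mice. Control mouse10372, labelled female, had 173 to 295 CPM of the Y-linked gene Ddx3y and 0.192 to 1.82 CPM of Xist, the RNA of the inactive X chromosome, over its 4 libraries. Control mouse10381, labelled male, had 203 to 321 CPM of Xist and 0 to 0.487 CPM of Ddx3y. Both belong to the control group under either label.

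Mbd3 was close to absent in the libraries labelled as deleted. The gene lies on chromosome 10 from 80392539 to 80399550 on the minus strand (ENSMUSG00000035478.14). Control means were 16.3 ± 5.19 CPM in HSCs, 41.2 ± 12.6 in LMPPs, 58.3 ± 51.9 in ALPs and 45.4 ± 15.9 in BLPs (SD, n = 5 each). Mbd3del counts per gene count were 0.704% of control in HSCs (counting interval 0.145% to 2.07%, 3 against 458 counts), 1.24% in LMPPs (0.708% to 2.02%), 1.93% in ALPs (1.33% to 2.73%) and 0.717% in BLPs (0.343% to 1.32%). The highest Mbd3del library had 2.96 CPM and the lowest control library 7.67 CPM, so the 20 libraries of each genotype did not overlap. The edgeR test called Mbd3 in HSCs (adjusted p = 0.0365), LMPPs (0.00986) and BLPs (0.0105) but not in ALPs (adjusted p = 0.128), where control levels ranged from 17.7 to 145 CPM. In ALPs the DESeq2 adjusted p was 8.07e-10, and the edgeR adjusted p was 0.0235 without Mbd3del mouse10376.

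**Figure D2:**
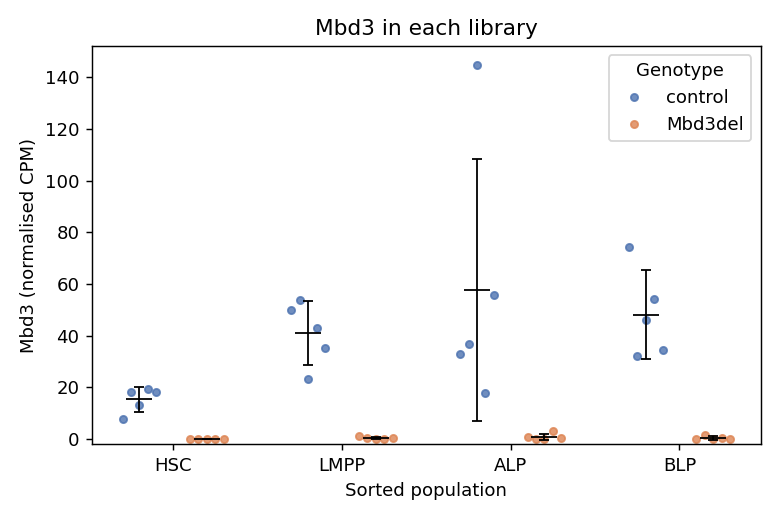
Mbd3 expression in each library in normalised CPM, by population and genotype. Points are libraries and bars show the mean ± SD (n = 5); Mbd3del libraries reach at most 2.96 CPM and control libraries start at 7.67 CPM.

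Pxdn, which encodes a peroxidase that crosslinks collagen IV of basement membranes, was higher in Mbd3del HSCs than in control HSCs. It had 17.0 ± 8.32 CPM in Mbd3del HSCs and 0.137 ± 0.141 CPM in control HSCs (SD, n = 5 each). Its 443 counts against 3 give a ratio of 159 with a counting interval of 53.9 to 772. The gene lies on chromosome 12 from 29937608 to 30017658 (plus strand). Interferon response genes were lower as a list in Mbd3del HSCs: 6 of 25 had a positive and 19 a negative fold change, with a median of -0.44 (camera adjusted p = 0.00208, but adjusted p = 0.187 with an estimated correlation). Of these, Ifi44 had 186 CPM in Mbd3del against 352 CPM in control HSCs, and Gbp2 had 119 against 219 CPM. Dendritic cell genes were higher as a list, with 7 of 7 tested members positive and a median of 0.36 (camera adjusted p = 0.00432, but adjusted p = 0.178 with an estimated correlation). H2-Ab1 and H2-Aa, subunits of MHC class II, had 155 against 86.1 CPM and 156 against 85.7 CPM. Genes for homing to the thymus were also higher, with 5 of 5 positive (camera adjusted p = 0.0177, but adjusted p = 0.178 with an estimated correlation), among them the chemokine receptor gene Cxcr4 at 109 against 11.1 CPM. The thymus homing call was lost without control mouse10357 (camera adjusted p = 0.0625), mouse10380 (0.0762) or mouse10381 (0.0547) or Mbd3del mouse10361 (0.0647).

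Of 11358 genes tested in HSCs, edgeR called 1 higher and 1 lower (Mbd3), 467 had an unadjusted p under 0.05 (568 expected with no change), and DESeq2 called 14. The edgeR count was 4 without the expression filter or in the joint fit of all 40 libraries, and 0 with a filter at 50 counts or with labelled sex as a covariate. The labelled sex goes against the sex-linked transcripts of control mouse10372 and mouse10381. Limma voom also called 0. The log2 fold change of Pxdn was 6.89 ± 1.03 (SE), with an edgeR adjusted p = 0.0418. With Mbd3, which the deletion itself changes, left out of the genes tested, edgeR called 0 genes (adjusted p = 0.0837 for Pxdn). No interferon response member was called over all genes or adjusted over the list alone, and 2 dendritic cell genes and 1 thymus homing gene passed adjusted over the list alone. The megakaryocyte and platelet list (camera adjusted p = 0.954), the stromal and endothelial list (0.722) and the stem cell list (0.954) were not called. Both gene calls were lost when any 1 of the 10 libraries was left out, with 0 genes called each time (edgeR adjusted p 0.0687 to 0.186 for Pxdn and 0.0662 to 0.161 for Mbd3). They were also lost without control mouse10372 and mouse10381 together (0.300 for each), when the thymus homing list was lost as well (camera adjusted p = 0.0910).

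In LMPPs Lgals1, which encodes the carbohydrate-binding protein galectin-1, was lower in every Mbd3del library than in every control library. It had 13.6 ± 5.23 CPM in Mbd3del LMPPs and 194 ± 87.7 CPM in control LMPPs (SD, n = 5 each). The gene (ENSMUSG00000068220.5) lies on chromosome 15 from 78926725 to 78930465 on the plus strand. Stem cell genes were higher as a list in Mbd3del LMPPs, with 16 of 19 positive and a median log2 fold change of 0.61 (camera adjusted p = 0.00105, but adjusted p = 0.108 with an estimated correlation). An example is the transcription factor gene Hlf, at 312 CPM against 182. Dendritic cell genes were again higher, with 7 of 7 positive and a median of 0.92 (camera adjusted p = 0.00155, but adjusted p = 0.0884 with an estimated correlation), including H2-Aa at 93.1 against 17.9 CPM. H2-Ab1 had 185 against 97.4 CPM.

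The edgeR test called 2 genes lower and 0 higher of 10918 in LMPPs, 567 had an unadjusted p under 0.05 (546 expected with no change), and DESeq2 called 36; without scaling of library totals edgeR called 3 higher and 3 lower, in the joint fit 4 and 4, and with its newer estimator 5 and 5. Lgals1 had a log2 fold change of -3.83 ± 0.42 (SE) with an edgeR adjusted p = 0.00524, and was called without each of the 10 libraries in turn. It was the 1 gene called with Mbd3 left out of the genes tested. No member of the stem cell or dendritic cell list passed over all genes or adjusted over the list alone. The macrophage list was not called (camera adjusted p = 0.924). The LMPP count was 4 without control mouse10357 or mouse10380, and 1 without control mouse10358 or Mbd3del mouse10361 or mouse10384. In these last 3 cases the call of Mbd3 was lost (edgeR adjusted p = 0.0505, 0.0657 and 0.0532). Lgals1 in the other populations had log2 fold changes of -1.98 in HSCs (edgeR adjusted p = 0.0722), -1.50 in ALPs (0.444) and 0.35 in BLPs (0.903), and no interaction with a step passed the threshold (edgeR adjusted p of 0.509 or above).

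In ALPs Cd63 and Serpinf1 were higher in every Mbd3del library than in every control library. Cd63, a tetraspanin of late endosomes and secretory granules, had 99.0 ± 29.9 CPM in Mbd3del and 11.4 ± 5.53 CPM in control ALPs (SD, n = 5 each). Serpinf1, which encodes the secreted factor PEDF, had 209.7 ± 30.7 against 48.3 ± 11.7 CPM. Cd63 lies on chromosome 10, as Mbd3 does, from 128900989 to 128912822 (plus strand), 48.5 megabases from Mbd3, and Serpinf1 on chromosome 11 from 75409769 to 75422701 (minus strand). Dendritic cell genes were higher as a list, with 7 of 10 positive and a median log2 fold change of 0.79 (camera adjusted p = 0.00148, but adjusted p = 0.0585 with an estimated correlation), for example Cd74, the MHC class II invariant chain, at 167 against 60.4 CPM. Interferon response genes were lower, with 21 of 24 negative and a median of -0.53 (camera adjusted p = 0.00501, but adjusted p = 0.237 with an estimated correlation). The B lineage list was called higher by camera (adjusted p = 0.0219, but adjusted p = 0.237 with an estimated correlation) while 9 of 18 members were positive and 9 negative. Mzb1, expressed in B cells and plasma cells, had 60.4 ± 25.1 against 12.5 ± 4.75 CPM, and Ly6d, the transcript of the protein whose absence defined the ALP gate, had 279 ± 158 against 84.0 ± 22.9 CPM. Neither passed over all genes (edgeR adjusted p = 0.374 and 0.815).

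Of 11009 genes tested in ALPs, edgeR called 2 higher and 0 lower, 253 had an unadjusted p under 0.05 (550 expected with no change), and DESeq2 called 14. In the joint fit edgeR called 6 higher and 3 lower, with its newer estimator 3 and 1, and with labelled sex as a covariate 1 and 0. The log2 fold change was 2.12 ± 0.26 (SE) for Serpinf1 (edgeR adjusted p = 0.00947) and 3.11 ± 0.45 for Cd63 (edgeR adjusted p = 0.0265). Cell cycle genes (21 of 28 positive, camera adjusted p = 0.0143, and adjusted p = 0.634 with an estimated correlation) and immediate early and heat shock genes (11 of 12 positive, camera adjusted p = 0.0485, and adjusted p = 0.637 with an estimated correlation) were also called higher by camera. Of the 5 lists, adjusted over the list alone, 1 B lineage gene passed. The ALP count was 0 without control mouse10357 or mouse10358 or Mbd3del mouse10361, 1 without control mouse10381 or Mbd3del mouse10360, mouse10365 or mouse10384, and 4 without Mbd3del mouse10376. Serpinf1 was lost in the first 3 of these (edgeR adjusted p = 0.0599, 0.0674 and 0.0675) and Cd63 in the first 7 (0.0564 to 0.165). Camera calls were lost for B lineage without control mouse10357, mouse10358 or mouse10372 or Mbd3del mouse10360 or mouse10384 (adjusted p 0.0513 to 0.191) and for cell cycle without control mouse10372 or mouse10380 or Mbd3del mouse10376 (0.204 to 0.347). They were lost for immediate early genes without control mouse10357, mouse10380 or mouse10381 or Mbd3del mouse10361, mouse10365 or mouse10376 (0.0663 to 0.741), and for the B lineage, cell cycle, immediate early and interferon response lists without control mouse10372 and mouse10381 together (0.131 to 0.137).

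In BLPs 8 of 10772 genes differed between genotypes, the most of the 4 genotype comparisons in the main fit, although LMPPs had more calls than BLPs without scaling of library totals. Cd63 was again higher in Mbd3del, at 65.6 ± 29.5 CPM against 7.61 ± 2.72, as was Cd68, a glycoprotein of lysosomes in myeloid cells, at 169 ± 84.6 against 23.3 ± 9.36 CPM (SD, n = 5 each). Ly6c2, a surface protein of monocytes and plasmacytoid dendritic cells, had 193 ± 126 against 29.1 ± 12.4 CPM. Rrm2, the small subunit of ribonucleotide reductase needed for DNA synthesis, had 615 ± 91.2 against 226 ± 80.2 CPM, and Prr13 had 566 ± 88.0 against 180.3 ± 79.3 CPM. Nckap1, an actin regulator of the WAVE complex, had 369 counts against 2, a ratio of 203 with a counting interval of 55.9 to 1685. Cpq, a carboxypeptidase, was lower, at 0.687 ± 0.539 against 23.6 ± 16.4 CPM. Counts of Ly6c2 are uncertain because a similar gene can share its reads.

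Cell cycle genes were higher as a list in Mbd3del BLPs, with 28 of 28 positive and a median log2 fold change of 0.78 (camera adjusted p = 2.88e-19, but adjusted p = 0.0625 with an estimated correlation). Besides Rrm2, Pcna had 427 against 248 CPM and Ccna2, cyclin A2, had 205 against 62.5 CPM. Dendritic cell genes were higher with 10 of 10 positive and a median of 1.12 (camera adjusted p = 9.38e-10, but adjusted p = 0.0625 with an estimated correlation), including the transcription factor gene Irf8 at 1153 against 619 CPM. Of the neutrophil and monocyte list 9 of 11 were positive, among them the chemokine receptor gene Ccr2 at 9.25 against 0.272 CPM, and of the NK and innate lymphoid list 4 of 5, among them Id2, an inhibitor of E proteins, at 75.0 against 27.8 CPM. These lists had a camera adjusted p of 0.00525 and 0.00266, but adjusted p = 0.0625 for each with an estimated correlation. Interferon response genes were lower (18 of 24 negative), as were stem cell genes (7 of 11 negative, Hoxa9 at 56.2 against 120 CPM) and lymphoid priming genes (13 of 17 negative, the recombinase gene Rag2 at 343 against 493 CPM). The camera adjusted p of these 3 lists was 0.00360, 0.00460 and 0.00825, but adjusted p = 0.233, 0.134 and 0.134 with an estimated correlation. The B lineage list was not called: 9 of 27 members were positive, Ebf1 had 158 against 229 CPM (edgeR adjusted p = 0.560), and Il7r, a sort marker, had 602 against 1008 CPM (edgeR adjusted p = 0.273).

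The edgeR test called 6 genes higher and 2 lower in BLPs, 895 had an unadjusted p under 0.05 (539 expected with no change), and DESeq2 called 158. Without scaling edgeR called 2 higher and 1 lower, without the expression filter 17 and 5, in the joint fit of all 40 libraries 16 and 15, and with its newer estimator 46 and 12. Log2 fold changes were 3.12 ± 0.41 (SE) for Cd63 and 2.87 ± 0.39 for Cd68 (edgeR adjusted p = 0.0105 for each), 2.73 ± 0.43 for Ly6c2 and 1.44 ± 0.22 for Rrm2 (0.0384 for each), 1.65 ± 0.27 for Prr13 (0.0422), 7.21 ± 1.22 for Nckap1 (0.0488) and -5.06 ± 0.85 for Cpq (0.0478). The genes lie on chromosome 11 from 69664213 to 69666153 (Cd68), chromosome 15 from 75108158 to 75111970 (Ly6c2), chromosome 12 from 24708241 to 24714146 (Rrm2), chromosome 15 from 102459028 to 102462806 (Prr13), chromosome 2 from 80500512 to 80581380 (Nckap1) and chromosome 15 from 33083129 to 33594552 (Cpq). With Mbd3 left out of the genes tested 4 genes were called, and Prr13 (edgeR adjusted p = 0.0506), Nckap1 (0.0558) and Cpq (0.0558) were lost. Of the cell cycle list 1 gene was called over all genes and 9 adjusted over the list alone, and of the dendritic cell list 1 and 4. None of the 17 list calls in the 4 genotype comparisons held with an estimated correlation. The lists not called were B lineage (camera adjusted p = 0.0802), NuRD complex (0.0738, negative by the test although its median was 0.03), sort markers (0.439), T lineage (0.192), thymus homing (0.153), erythroid (0.0526), immediate early and heat shock (0.0526), mature B and plasma cell (0.170), p53 targets (0.217) and imprinted genes (0.217). The BLP count was 0 without control mouse10380, 43 without control mouse10357, 3 without control mouse10358 or Mbd3del mouse10360, mouse10361 or mouse10365, and 5 without Mbd3del mouse10376 or mouse10384. Cd63, Cd68 and Mbd3 were lost only without control mouse10380 (edgeR adjusted p = 0.0554 for each). Of the other 5 genes, each was called without control mouse10357 and otherwise at most once, Ly6c2 and Rrm2 without Mbd3del mouse10376, Prr13 without control mouse10372 and Cpq without control mouse10381 (lost calls 0.0554 to 0.155). Without control mouse10372 and mouse10381 together 1 gene was called, which was none of the 8. The interferon response (camera adjusted p = 0.0712), lymphoid priming (0.0712) and stem cell (0.162) lists were then lost. The B lineage list was called lower (5.52e-04), as it was without control mouse10372 (0.00627), mouse10380 (0.0208) or mouse10381 (0.0341) or Mbd3del mouse10361 (0.0459) or mouse10384 (0.0318) alone.

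**Figure D3:**
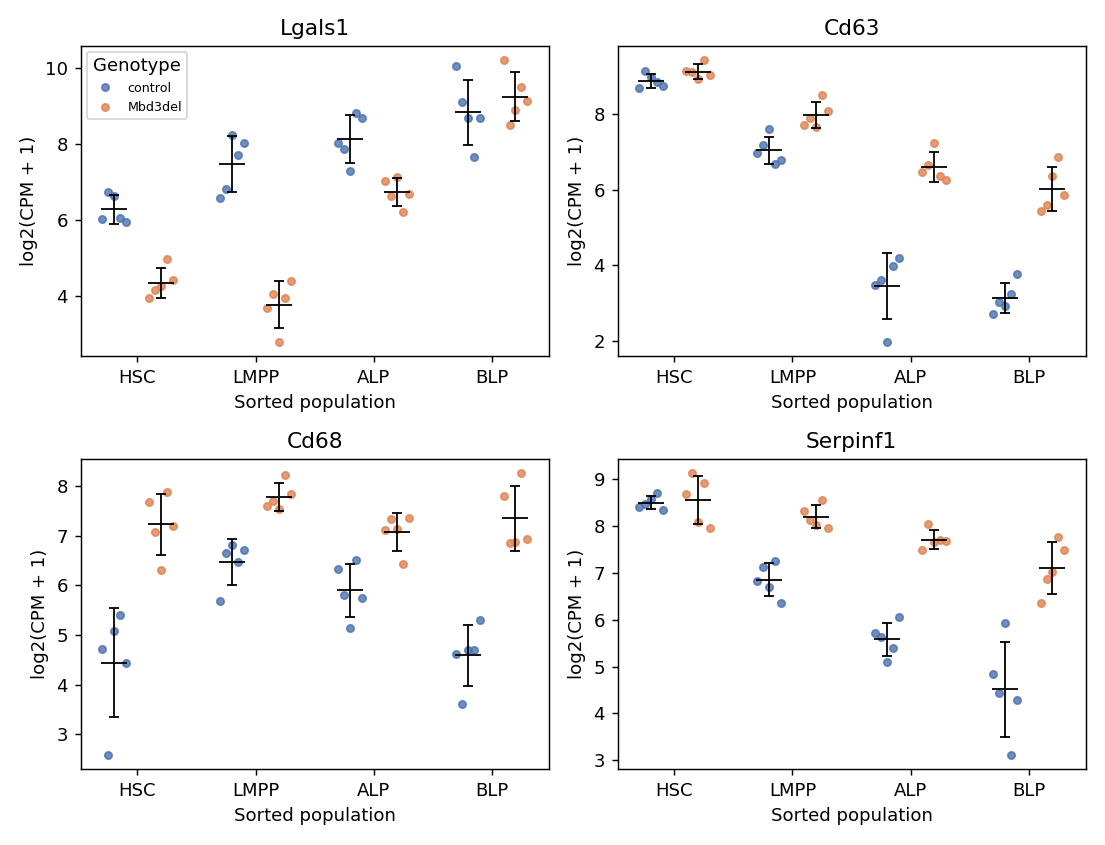
Expression of Lgals1, Cd63, Cd68 and Serpinf1 in each library as log2(CPM + 1), by population and genotype. Points are libraries and bars show the mean ± SD (n = 5); Lgals1 was called in LMPPs, Cd63 in ALPs and BLPs, Serpinf1 in ALPs and Cd68 in BLPs.

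Calls shared between populations were few. Mbd3 was the shared lower gene of HSCs and LMPPs, HSCs and BLPs, and LMPPs and BLPs. Cd63 was the shared higher gene of ALPs and BLPs, 1 gene where independent lists of 2 and 5 genes among 10434 would share 9.58e-04. The mice are the same in all populations.

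The B lineage score, a mean over 27 genes of B cell specification, went along the path in control libraries from 1.81 ± 0.121 in HSCs to 2.09 ± 0.178 in LMPPs, 3.32 ± 0.0864 in ALPs and 5.79 ± 0.774 in BLPs (SD, n = 5 each; these differences were not tested by permutation). In Mbd3del ALPs the score was 3.66 ± 0.233, a difference of 0.34 on the log2 scale (exact permutation p = 0.0317, adjusted p = 0.127 over 4 populations). The Mbd3del score was 5.63 ± 0.385 in BLPs, a difference of -0.17 (exact permutation p = 0.667), 1.78 ± 0.118 in HSCs (-0.03, exact permutation p = 0.714) and 2.15 ± 0.245 in LMPPs (0.05, exact permutation p = 0.722). No difference passed the adjusted threshold; the ALP difference did so without Mbd3del mouse10365 (0.42, exact permutation adjusted p = 0.0317) and, at 0.20, with a pseudocount of 5 (exact permutation adjusted p = 0.0317).

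**Figure D4:**
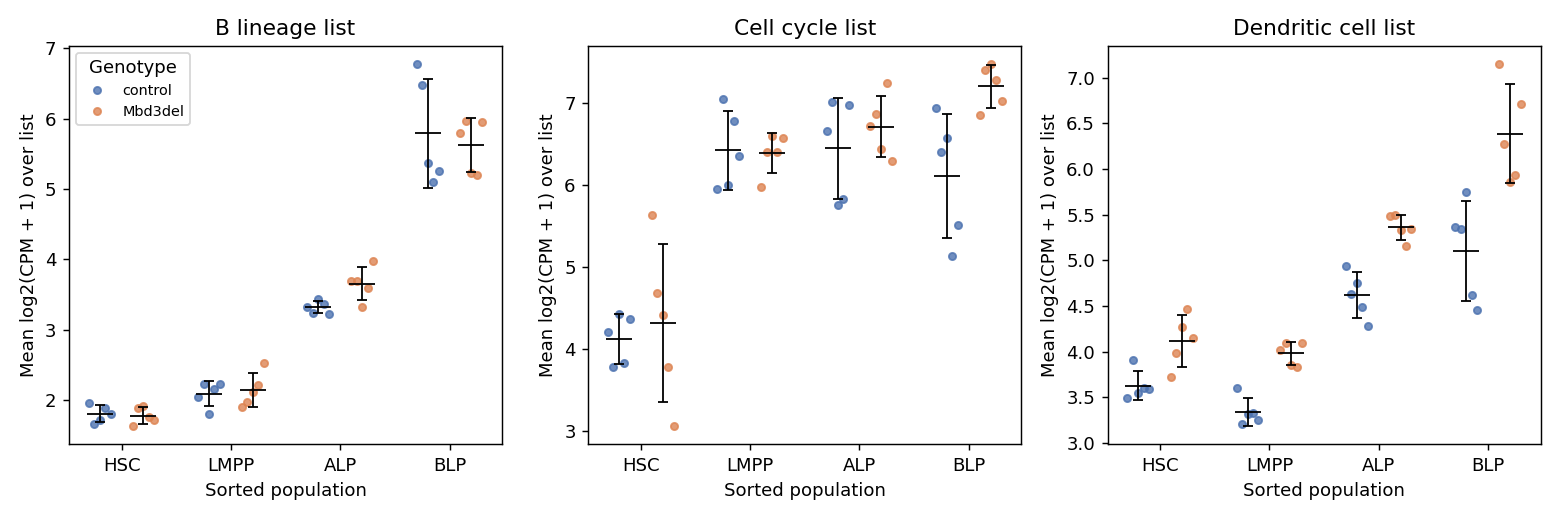
Mean log2(CPM + 1) over the B lineage, cell cycle and dendritic cell lists in each library, by population and genotype. Points are libraries and bars show the mean ± SD (n = 5); the B lineage score of control libraries goes from 1.81 in HSCs to 5.79 in BLPs.

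Genes that separate control BLPs from control HSCs were used to ask whether Mbd3del LMPPs and ALPs lay nearer to the stem cell or to the B-biased end. In LMPPs, of the 100 genes most clearly higher in control BLPs, 84 were tested and 50 were lower in Mbd3del (camera adjusted p = 0.00239, and adjusted p = 0.0250 with an estimated correlation). With lists of 50 or 200 genes this call was lost with an estimated correlation (adjusted p = 0.0691 and 0.124). Of the 100 genes lower in control BLPs, 78 were tested and 53 were higher in Mbd3del LMPPs (camera adjusted p = 0.00216, but adjusted p = 0.155 with an estimated correlation). In ALPs the genes higher in BLPs were not called (camera adjusted p = 0.672), and 32 of 57 genes lower in BLPs were higher in Mbd3del (camera adjusted p = 0.00599, and adjusted p = 0.0411 with an estimated correlation). With an estimated correlation the ALP call was lost with a list of 50 genes (adjusted p = 0.0847) and kept with 200 (adjusted p = 0.0467). The lists come from other libraries of the same control mice.

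From HSC to LMPP in control mice, genes of stem cells fell and genes of proliferation and lymphoid priming rose. Of 22 stem cell genes 16 fell and 1 rose: Tek, the angiopoietin receptor gene, went from 93.4 ± 15.7 to 0.0259 ± 0.0579 CPM and Mllt3 from 707 ± 106 to 22.6 ± 10.3 CPM (SD, n = 5 each). Of 28 cell cycle genes 18 rose, with Top2a going from 27.7 ± 8.53 to 261 ± 48.8 CPM. Of 16 lymphoid priming genes 5 rose, led by Dntt, the terminal transferase of antigen receptor joints, from 19.3 ± 5.04 to 1217 ± 392 CPM. Of the neutrophil and monocyte list 2 rose, Mpo from 1.99 to 514 CPM and Ctsg from 0.330 to 109 CPM. The largest rises were of Gcsam (at least 315-fold), Cd300lb (at least 210-fold), Ms4a4c (at least 178-fold), Sgo2a (at least 162-fold) and Slc18a1 (at least 150.1-fold), all with 0 counts in control HSCs, and of Slc16a11. The largest falls were of Nupr1 (at least 812-fold), Slc6a15 (at least 647-fold), Aldh1a1, a retinaldehyde dehydrogenase gene (at least 584-fold), Clca3a1 (at least 538-fold) and Clec1a (at least 490.1-fold), with 0 counts in control LMPPs, and of Slamf1. Slamf1 encodes CD150, the marker that defined the HSC gate, and had 3653 counts against 1, and Cd48, whose protein was absent by the HSC gate, rose from 2.62 to 631 CPM.

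The edgeR test called 311 genes higher and 351 lower of 11043 in this step. Among the lists, the camera adjusted p was 6.06e-25 for stem cell genes (17 lower adjusted over the list alone), 5.56e-24 for cell cycle (24), 1.90e-11 for lymphoid priming (7), 1.05e-05 for neutrophil and monocyte genes, 5.30e-05 for falling megakaryocyte and platelet genes, 9.22e-04 for falling imprinted genes and 0.00933 for rising thymus homing genes. These 7 calls held with an estimated correlation (adjusted p 1.63e-04 to 0.0496), and those of B lineage (0.00508, then adjusted p = 0.0976 with an estimated correlation) and NuRD genes (0.0162, then adjusted p = 0.130 with an estimated correlation) did not. With mouse as a block, 11 of the 12 genes of largest fold and 57 of 69 called list genes kept their call, Slc18a1 being lost (edgeR adjusted p = 0.0561). Leaving out control mouse10381 gave 431 genes and the NuRD list was lost without control mouse10358 (camera adjusted p = 0.0626).

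From LMPP to ALP in control mice, genes of lymphoid commitment rose and stem cell genes fell. Il7r, whose protein defined the ALP gate, went from 3.12 ± 2.30 to 576 ± 157 CPM and Dntt from 1205 ± 388 to 6794 ± 1470 CPM (SD, n = 5 each). Of 14 B lineage genes 4 rose, among them Ebf1, the transcription factor that specifies B cells, from 0.118 ± 0.112 to 25.6 ± 14.6 CPM, and Blnk from 16.4 to 355 CPM. Of 9 dendritic cell genes 2 rose, Siglech from 0.726 to 69.4 CPM and Irf8 from 35.3 to 543 CPM. The falling genes included Hlf, from 179 to 11.9 CPM, Car2, carbonic anhydrase 2, from 1373 to 98.1 CPM, and Prtn3, a neutrophil protease gene, from 221 to 10.5 CPM. The largest rises were of Mycl, Tmem119, Cd6, Sema4a, Xkrx and Tnfsf11, with Tmem119 going from 0.195 to 61.7 CPM, and large falls were those of Rgs11 (at least 152-fold) and Nqo1 (at least 108-fold), with 0 counts in control ALPs, and of Rnf217, S100a8 and Cav2.

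The edgeR test called 51 genes higher and 51 lower of 10871. By list, the camera adjusted p was 5.56e-09 for B lineage (5 higher adjusted over the list alone), 2.20e-09 for stem cell genes (6 lower), 4.04e-09 for lymphoid priming (8 higher), 7.09e-08 for T lineage (4 higher) and 1.75e-06 for dendritic cell genes (2 higher), and these 5 calls held with an estimated correlation (adjusted p 0.00326 to 0.0406). Those of NuRD, sort marker, thymus homing, neutrophil and monocyte, erythroid, mature B and plasma cell and interferon response genes (0.00179 to 0.0408) did not (adjusted p 0.0601 to 0.180 with an estimated correlation), and the sort markers, which hold the gate's own Il7r and were called higher with a median of -0.14, were also lost with mouse as a block (0.151) and without control mouse10357 (0.113), mouse10372 (0.0688) or mouse10380 (0.242), as was the erythroid list without control mouse10357 (0.0842), mouse10358 (0.0525) or mouse10381 (0.0596). With mouse as a block 54 genes were called, among them 3 of the 12 genes of largest fold (Mycl, Tmem119 and Cav2) and 13 of 22 called list genes, and Ebf1 had an edgeR adjusted p = 0.0672. The count was 52 without control mouse10357, 44 without mouse10358 and 39 without mouse10381, and 5 of the 12 genes of largest fold and 8 of 22 list genes, Il7r, Dntt, Ebf1, Siglech, Irf8, Hlf, Car2 and Prtn3, kept their call without each mouse, while Blnk lost it without control mouse10357 (edgeR adjusted p = 0.0799) or mouse10372 (0.0502).

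From ALP to BLP in control mice, the B cell programme rose. Ly6d, whose protein defined the BLP gate, went from 82.6 ± 22.4 to 8092 ± 3125 CPM (SD, n = 5 each). Of 24 B lineage genes 23 were positive and 10 rose, with a median log2 fold change of 2.51. Ebf1 went from 25.5 ± 14.5 to 237 ± 42.3 CPM, Mzb1 from 12.3 ± 4.70 to 196 ± 73.2 CPM, Chchd10 from 36.9 to 315 CPM and Cd79a, a subunit of the B cell receptor, from 1.67 to 255 CPM. The largest rises were of Trat1 (at least 130.1-fold, with 0 counts in control ALPs), Vpreb3, Pou2af1, Gfra2, Dlg2 and Ighv10-3, with Vpreb3 going from 0.306 to 169 CPM. Wfdc17, Gcnt2 and Cd34, a marker of early progenitors, fell, Cd34 from 1022 ± 164 to 353 ± 87.2 CPM. Neutrophil and monocyte genes were lower as a list, with 9 of 10 negative.

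The edgeR test called 26 genes higher and 3 lower of 10905. List by list, the camera adjusted p was 1.46e-57 for B lineage (16 higher adjusted over the list alone) and 2.23e-06 for neutrophil and monocyte genes (1 lower adjusted over the list alone), and these held with an estimated correlation (adjusted p = 3.54e-04 and 0.0194). The sort markers (2.23e-06, and adjusted p = 0.0437 with an estimated correlation) hold Ly6d itself (log2 fold change 6.61), which the gate fixes. Of the other 6 tested, Ly6a (0.90), Il7r (0.86) and Ptprc (0.11) were positive and Kit (-0.80), Flt3 (-0.69) and Cd48 (-0.12) negative, and none passed over all genes (edgeR adjusted p of 0.660 or above). The calls of lymphoid priming, stem cell, dendritic cell, cell cycle and interferon response genes (0.00130 to 0.0370) did not (adjusted p 0.0746 to 0.589 with an estimated correlation), and were lost for stem cell genes without control mouse10357 (0.0709), for cell cycle without mouse10358, mouse10380 or mouse10381 (0.238 to 0.663) and for interferon response without mouse10372 or mouse10380 (0.168 and 0.375). With mouse as a block 14 genes were called, among them 4 of the 9 genes of largest fold (Vpreb3, Pou2af1, Dlg2 and Wfdc17) and 7 of 12 called list genes, while Trat1 (edgeR adjusted p = 0.489), Gfra2 (0.186), Ighv10-3 (0.336), Gcnt2 (0.103) and Cd34 (0.0793) were lost. The count was 10 without control mouse10357 or mouse10381 and 8 without mouse10358, and Vpreb3, Dlg2 and 5 list genes (Ly6d, Mzb1, Ebf1, Chchd10 and Cd79a) kept their call without each mouse, while Cd34 and Wfdc17 lost theirs without any of these 3 (edgeR adjusted p 0.0606 to 0.186) and Pou2af1 without mouse10358 (0.0606).

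The same steps in Mbd3del mice changed many of the genes that changed in control mice. In Mbd3del mice 340 genes rose and 426 fell from HSC to LMPP, 123 rose and 119 fell from LMPP to ALP, and 55 rose and 14 fell from ALP to BLP, where Ly6d went from 270.0 ± 153 to 10264 ± 4009 CPM and Cd79a from 11.9 ± 3.86 to 238 ± 102 CPM (SD, n = 5 each). From HSC to LMPP 172 rising and 192 falling genes were shared with control mice, where independent lists would share 8.96 and 11.9. From LMPP to ALP 37 and 36 were shared (0.525 and 0.484 for independent lists), and from ALP to BLP 15 and 2 (0.129 and 0.00345). With mouse as a block the Mbd3del totals were 154 from LMPP to ALP and 41 from ALP to BLP. The LMPP to ALP total was 121 without mouse10360 and 125 without mouse10361. From ALP to BLP it was 17 without mouse10360, 26 without mouse10361, 40 without mouse10365 or mouse10384 and 43 without mouse10376, and from HSC to LMPP it was 507 without mouse10361.

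Tested directly, the difference of a step between genotypes was called for no single gene by edgeR and for 6 list tests by camera, and none of these 6 held with an estimated correlation (adjusted p 0.0702 to 0.695). In the step from ALP to BLP the B lineage list changed less in Mbd3del mice by camera, with 20 of 27 members negative and a median difference of -0.41 (camera adjusted p = 7.73e-04, but adjusted p = 0.239 with an estimated correlation): Mzb1 went from 58.9 to 226 CPM in Mbd3del against 12.2 to 193 CPM in control mice, and Cd79a from 11.99 to 239 against 1.65 to 251 CPM. Neither gene passed alone (edgeR adjusted p = 0.515 or above). Cell cycle genes went the other way, with 26 of 28 positive (camera adjusted p = 8.11e-07, but adjusted p = 0.239 with an estimated correlation), for example Ccna2 from 69.5 to 210 CPM in Mbd3del against 78.3 to 63.95 CPM in control mice. The stem cell list changed less from HSC to LMPP in Mbd3del mice, with 17 of 22 positive and a median of 0.46 (camera adjusted p = 0.00264, but adjusted p = 0.0702 with an estimated correlation).

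The edgeR interaction test called 0 of 12576 genes for HSC to LMPP, 0 of 12237 for LMPP to ALP and 0 of 12123 for ALP to BLP, where 645, 552 and 489 genes had an unadjusted p under 0.05 (629, 612 and 606 expected with no change) and DESeq2 called 27, 17 and 10. Of the B lineage list from ALP to BLP 1 gene passed, lower, adjusted over the list alone. Lymphoid priming (0.0331, then adjusted p = 0.247 with an estimated correlation) and dendritic cell genes (0.0357, then adjusted p = 0.267 with an estimated correlation) from ALP to BLP and cell cycle genes from LMPP to ALP (0.0133, then adjusted p = 0.695 with an estimated correlation) were called by camera too. Lymphoid priming was lost without control mouse10357, mouse10358 or mouse10381 or Mbd3del mouse10360, mouse10361 or mouse10376 (camera adjusted p 0.0565 to 0.118), dendritic cell genes without control mouse10358, mouse10380 or mouse10381 or Mbd3del mouse10360 or mouse10376 (0.0548 to 0.133), and the LMPP to ALP cell cycle list without control mouse10380 (0.431) or Mbd3del mouse10360 (0.108) or mouse10376 (0.503). The HSC to LMPP gene count was 1 without control mouse10357, mouse10358 or mouse10381, 3 without control mouse10380 and 2 without Mbd3del mouse10376.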

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

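Here the tests of the cell cycle list and of the sex labels, and those with Mbd3 left out, were chosen only after the results were seen; the list interactions and the other counts over splits were planned.

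Single libraries stood apart from the other 4 of their group in 4 of 79 groups tested by the gap to the nearest library over the range of the group, where chance gives 3.95 (about 1 in 20 groups). Ribosomal protein transcripts took 1.52% of counts in control mouse10372 BLPs against 2.004% to 2.05% in the others (gap over range 0.918). They took 2.89% in control mouse10381 LMPPs against 2.08% to 2.23% (0.814). The 10 most counted genes took 10.3% in control mouse10381 BLPs against 7.13% to 8.04% (0.712). Ly6c2 had 433 CPM in Mbd3del mouse10360 BLPs against 120 to 201 CPM in the others (0.740). Without that library Ly6c2 was not called (edgeR adjusted p = 0.0939).

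For 6 gene lists the change over a step differed between genotypes by the camera test of the interaction, and none of the 6 passed with an estimated correlation (adjusted p 0.0702 to 0.695). From ALP to BLP the cell cycle list changed upwards in Mbd3del relative to control mice (adjusted p = 8.11e-07), as did dendritic cell genes (0.0357), while B lineage (7.73e-04) and lymphoid priming genes (0.0331) changed downwards. From LMPP to ALP the cell cycle list (0.0133) and from HSC to LMPP the stem cell list (0.00264) changed upwards.

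In Mbd3del BLPs 28 of 28 cell cycle genes were higher, with a median log2 fold change of 0.78 (camera adjusted p = 0.0625 with an estimated correlation). At the preset correlation the call did not rest on a single library, since the adjusted camera p without each library in turn was at most 2.23e-14, without control mouse10380. The members varied together between libraries within the genotypes (estimated correlation 0.329), so that the list counts as fewer independent genes. Whether this accounts for the call stays open: the list score was 7.20 ± 0.261 in Mbd3del and 6.11 ± 0.756 in control BLPs (SD, n = 5 each; exact permutation adjusted p = 0.0529 over 20 lists, or 0.0635 with Mbd3 taken out of the NuRD list). A higher share of dividing cells in Mbd3del BLPs is a hypothesis that these tests leave undecided.

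In 2 control mice the sex-linked transcripts went against the labelled sex, in 4 libraries each. An exchange with an Mbd3del mouse is excluded, since the lowest of the 8 libraries had 13.3 CPM of Mbd3 and the highest Mbd3del library 2.96 CPM. Mixed cells of both mice are excluded as well, since the lower of Xist and Ddx3y reached at most 1.82 CPM in these libraries and 3.37 CPM in the other 32. All 8 libraries show the sex labelled for the other mouse, which is consistent with labels exchanged between mouse10372 and mouse10381. A wrong sex record for each mouse separately would look the same, and no biological explanation was tested.

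Of 100 splits of the same libraries, the real split included, 1 gave as many genes (the real one) in HSCs (2 genes, highest other 1), LMPPs (2, highest other 1), ALPs (2, highest other 1) and BLPs (8, highest other 2). The HSC, LMPP and BLP counts hold Mbd3, which the deletion itself changes. In ALPs, where Mbd3 was not called, 253 genes had an unadjusted edgeR p under 0.05 (550 expected with no change). With Mbd3 left out of the genes tested, 1 of 100 splits gave as many in BLPs (4, highest other 2). Chance in how mice fell into groups can be excluded for that count. In ALPs it was also 1 of 100 (2, highest other 1), but counts this close do not alone exclude chance. In LMPPs 3 of 100 splits gave as many (1, highest other 1), a share under 0.05. Since 2 other splits reached the same count of 1 gene, the count alone does not exclude chance in LMPPs. In HSCs edgeR then called 0 genes (highest other 1), which 100 of 100 splits match whatever the data, so the splits decide nothing there; with Mbd3 included 467 genes had an unadjusted p under 0.05, where 568 are expected with no change, and DESeq2 called 14. For the control steps it was again 1 of 100: 662 genes from HSC to LMPP (highest other 1), 102 from LMPP to ALP (highest other 1) and 29 from ALP to BLP (highest other 2). For the Mbd3del steps 1 of 100 splits gave as many, with 766 genes (highest other 135), 242 (highest other 1) and 69 (highest other 4). Among the 16 splits that part every mouse's pair of libraries, as the real one does, the highest other gave 0 genes in the control steps and 1, 0 and 1 in the Mbd3del steps, and 16 splits are too few for a share under 0.05. The split with 135 genes was not among those 16. For the interactions the edgeR count was 0, which 100 of 100 splits match for each step whatever the data, so the splits decide nothing there either (highest others 5, 3 and 1; 645, 552 and 489 genes at an unadjusted p under 0.05, where 629, 612 and 606 are expected with no change, and 27, 17 and 10 called by DESeq2).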

How the results depend on the processing

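Among the settings below, the newer edgeR estimator, the fits without control mouse10372 and mouse10381, the average genotype effect, the tests with Mbd3 left out and the list tests with libraries left out were chosen only after the data were seen. Of 2132 values of named genes under other settings 1701 kept their direction and their side of the threshold, 419 were no longer called, 6 became called and 6 changed sign. Of 830 list values 723 kept both, 101 were no longer called, 6 became called and 0 changed direction. Mbd3 kept its direction in all 4 genotype comparisons under all settings run, and the DESeq2 size factors left every genotype count as it was. The cause of the changes that follow was not tested, except that leaving out libraries leaves fewer samples and a stricter filter fewer genes. Depth limits low genes: 3 counts correspond to 0.330 to 1.01 CPM in a library.

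In HSCs, where 2 genes were called, there were 4 without the expression filter, 14 with DESeq2, 4 in the joint fit of all 40 libraries and 1 with the newer estimator, which was neither Pxdn nor Mbd3. A filter at 50 counts gave 0, limma voom 0, labelled sex as a covariate 0, sex and age 0, and leaving out control mouse10372 and mouse10381 gave 0. In all fits with sex the covariate was the labelled sex, which goes against the sex-linked transcripts of these 2 mice. In LMPPs, where 2 were called, there were 6 without scaling (3 higher and 3 lower), 6 without the filter, 36 with DESeq2, 4 with limma voom, 8 in the joint fit and 10 with the newer estimator. In ALPs, where 2 were called, there were 14 with DESeq2, 1 with sex, 1 with sex and age, 9 in the joint fit and 4 with the newer estimator. In BLPs, where 8 were called, there were 3 without scaling, 22 without the filter, 158 with DESeq2, 31 in the joint fit (16 higher and 15 lower), 58 with the newer estimator and 1 without control mouse10372 and mouse10381. With Mbd3 left out of the genes tested, which removes 1 call where it was called and raises the adjusted p of others, there were 0 in HSCs, 1 in LMPPs, 2 in ALPs and 4 in BLPs.

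Leaving out 1 library gave 0 genes in each case in HSCs, 1 to 4 in LMPPs, 0 to 4 in ALPs and 0 to 43 in BLPs. Leaving out 1 mouse gave 431 to 738 genes from HSC to LMPP in control mice, 39 to 98 from LMPP to ALP and 8 to 33 from ALP to BLP. In Mbd3del mice the ranges were 507 to 618, 121 to 246 and 17 to 43. The interaction counts were 0 to 3 from HSC to LMPP and 0 in the other steps. Mbd3 itself was not called in these 2 control steps or in an interaction, and its log2 change without 1 mouse went from -0.35 to 0.75 from LMPP to ALP in control mice, -0.64 to 0.44 from ALP to BLP, -1.53 to 1.14 in the LMPP to ALP interaction and -2.0 to 0.60 in the ALP to BLP interaction.

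DESeq2 called 1137, 281 and 69 genes in the control steps, 1222, 474 and 207 in the Mbd3del steps, and 27, 17 and 10 in the interactions. Without scaling, the median log2 fold change of all genes was 0.11 in HSCs, 0.12 in LMPPs, -0.10 from HSC to LMPP and -0.13 from ALP to BLP in control mice, and -0.23 in the LMPP to ALP interaction.

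With mouse as a block, which the shared mice call for, 54 genes were called from LMPP to ALP and 14 from ALP to BLP in control mice, and 154 and 41 in Mbd3del mice. In this blocked fit Mbd3 had a log2 change of 0.026 from ALP to BLP in control mice and -0.15 in the LMPP to ALP interaction. Apart from the named genes given with their values, the blocked fit ended 1 list call in the control steps, that of sort markers from LMPP to ALP (camera adjusted p = 0.151).

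The B lineage score differed by 0.0037 in HSCs with a pseudocount of 5, by 0.0026 without scaling and by 0.00042 without Ebf1 and Pax5, against -0.03 as reported. In LMPPs a pseudocount of 5 gave -0.0018. In ALPs it gave 0.20, which passed (exact permutation adjusted p = 0.0317). Without 1 library the differences were -0.064 to 0.0097 in HSCs, -0.042 to 0.12 in LMPPs, 0.26 to 0.42 in ALPs and -0.34 to 0.080 in BLPs. The LMPP call of genes lower in control BLPs than HSCs was lost with an estimated correlation (adjusted p = 0.155). The average genotype effect, with 37 genes called by limma, gave 22 to 33 genes by limma without 1 mouse. With edgeR on summed counts it gave 24 genes.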

Other observations

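All tests in this part were chosen only after results of the planned comparisons were seen, and genes are named here after their values were seen.

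Averaged over the 4 populations of each mouse, 37 of 13800 genes differed between genotypes with limma, 23 higher and 14 lower in Mbd3del mice. Of these, 35 had the same sign in every population, Lgals1 and Nedd4 being the exceptions. The genes were called on the mean over these same populations, so the shared sign is partly built in and is not separate evidence. A shared sign does not mean a difference of similar size in each population. In HSCs the log2 difference was 0.037 for Apoe, 0.062 for Serpinf1 and 0.243 for Cd63, but 2.85 for Cd68 and 3.91 for Tjp1. Beside Mbd3 (-5.82), the lowest adjusted p belonged to Lgals1 (log2 fold change -1.68 ± 0.14, SE, adjusted p = 1.02e-05), Tjp1, a scaffold protein of tight junctions (4.71 ± 0.39, adjusted p = 1.12e-05), Cd63 (1.86 ± 0.16, adjusted p = 1.45e-05), Serpinf1 (1.55 ± 0.14, adjusted p = 2.86e-05), Cpq (-2.11 ± 0.21, adjusted p = 4.87e-05) and Cd68 (2.04 ± 0.21, adjusted p = 8.26e-05). Next in order of adjusted p were Gpr160 (-2.27), Apoe, an apolipoprotein made by macrophages and liver (2.95, limma adjusted p = 7.78e-04), Atp8b4 (-2.35) and Dbn1, an actin-binding protein (2.45). Sorted HSCs held Apoe as well, at 549 CPM in control and 575 CPM in Mbd3del mice, against 6.99 and 149 CPM in LMPPs. Among control groups Cd63 (476 CPM) and Serpinf1 (361 CPM) were also highest in HSCs, while Cd68 (25.1 CPM in HSCs) was not. Tdg, a thymine DNA glycosylase, was lower (-2.02, limma adjusted p = 0.0334). Summed counts tested with edgeR gave 24 genes, 13 of them among the 37. With limma on the averages, leaving out Mbd3del mouse10376 gave 22 genes, mouse10360 23, mouse10361 23 and mouse10365 24. Of 100 splits of the mice, 1 gave as many genes, the real one, and the highest other gave 1. With Mbd3 left out of the genes tested it was again 1 of 100 (36 genes, highest other 1), so chance can be excluded.

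On these averages 11 of 12 dendritic cell genes were positive with a median of 0.68, 1 of them called over all genes, Clec9a (2.25, limma adjusted p = 0.0132). The MHC class II genes H2-Aa (1.57, limma adjusted p = 0.0891) and H2-Eb1 (1.58, limma adjusted p = 0.0756) did not pass. Of the interferon response list 21 of 25 genes were negative with a median of -0.33, for example Zbp1 (-1.68, limma adjusted p = 0.195), and 28 of 28 cell cycle genes were positive with a median of 0.36. The dendritic cell (camera adjusted p = 6.02e-08, and adjusted p = 0.0116 with an estimated correlation) and interferon response calls (3.41e-07, and adjusted p = 0.0423 with an estimated correlation) held, and the cell cycle call did not (1.50e-06, and adjusted p = 0.385 with an estimated correlation).

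List scores compared in each population by exact permutation, adjusted over 20 lists, differed in BLPs for 4 lists beside the NuRD list, whose score holds Mbd3 itself, each at the smallest p the test can give (0.00794, adjusted p = 0.0317, or 0.0397 with Mbd3 taken out of the NuRD list) and with no overlap of the 5 and 5 libraries. Dendritic cell genes were higher in Mbd3del BLPs (6.39 ± 0.544 against 5.11 ± 0.547, SD), as were NK and innate lymphoid (4.46 ± 0.225 against 3.62 ± 0.275), neutrophil and monocyte (3.26 ± 0.138 against 2.52 ± 0.249) and T lineage genes (4.27 ± 0.124 against 3.95 ± 0.135). Without Mbd3 the NuRD score was 6.24 ± 0.0648 against 6.28 ± 0.188 (exact permutation p = 0.698). The stem cell and dendritic cell scores in LMPPs (exact permutation adjusted p = 0.0794 for each) and the dendritic cell score in ALPs (0.159) did not pass. These 3 scores had the same smallest p and no overlap either. Their adjusted p is higher because fewer lists reached that p, so the pass does not set BLPs apart for dendritic cell genes. In HSCs the dendritic cell score had an exact permutation p = 0.0159 (adjusted p = 0.317). The adjustment did not span the 4 populations.

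Macrophage RNA in the sorted cells was tested as the source of the genes called on the averages. It would raise the macrophage list by about the change of the called genes, a median of 2.19 for those higher, whereas its 6 members had a median of 0.0106 (SD 0.604), with 3 positive. C1qa had 0.915 CPM in Mbd3del and 0.523 in control libraries, C1qb 0.738 and 0.621 and C1qc 1.01 and 0.593, while Vcam1 had 2.95 and 0.381. The first 3 lie near the floor of 3 counts (0.330 to 1.01 CPM in a library). The list therefore cannot exclude this source for the 23 genes called higher in Mbd3del mice. Macrophage RNA added to Mbd3del libraries would not lower a gene, which argues against it for the 14 genes called lower, Mbd3 among them. Strain DNA carried along next to Mbd3 is excluded for the 34 of 36 genes other than Mbd3 that lie off chromosome 10, and stays open for Tdg, 2.23 megabases from Mbd3, and Cd63, 48.5 megabases from it, although the share on the chromosome was 5.56% against 4.65% of tested genes (Fisher's exact p = 0.684). Macrophage RNA, for the genes called higher, and unlinked strain variants in the mixed background stay open. A shared effect of Mbd3 loss on the called genes is therefore a hypothesis.

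The rows named repRegion were tested apart from genes. Of them 3077 had a count in HSCs, 3044 in LMPPs, 3596 in ALPs and 2889 in BLPs. Few of these passed the expression filter, so the tests do not speak for most repRegion rows. With edgeR 0 of 105 passed in HSCs, 0 of 112 in LMPPs, 0 of 122 in ALPs and 0 of 116 in BLPs, where 3, 4, 2 and 6 had an unadjusted p under 0.05 and 5.25, 5.6, 6.1 and 5.8 are expected with no change. The smallest adjusted p was 0.328, 0.915, 0.983 and 0.555.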
